A study of Mus musculus with 57 samples.

How the data were processed

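Whole-kidney RNA of 57 samples from 3 lupus-prone mouse strains was studied on Affymetrix arrays, with labelled cRNA made from total RNA per the labels' protocols. Samples were assigned to 8 groups from the labels: NZB/W at 16 weeks, prenephritic (n = 8), at 23 weeks, non-proteinuric (n = 11), at 23 weeks, proteinuria onset (n = 6) and at 36 weeks, nephritic (n = 10), NZM2410 prenephritic and nephritic (n = 5 each) and NZW/BXSB prenephritic and nephritic (n = 6 each). Labels of the 36-week group conflicted, since 1 field called those kidneys prenephritic while another described them as nephritic with proteinuria, and the latter was followed. Ages in weeks were stated for NZB/W alone, though titles call the prenephritic NZM2410 samples Young and the nephritic ones Sick.

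The deposited values were log2 expression levels, and the submitters' processing notes name RMA (robust multi-array average, which corrects background, normalizes between arrays and summarizes probes), version not given. The array type, the definition of the probe sets and a genome build were not given in the sources used here, so no coordinates are printed. Each strain had its own table of 16539 rows, 16475 genes with an Entrez gene ID and a symbol, 1 row each, and 64 array controls. A table of the whole series held the same values, the largest difference being 0. Gene IDs were matched to a RefSeq table of the mouse assembly GRCm38.p6, used for names only. In all, 16229 genes matched, 246 kept the name in the table, 2163 were renamed, and 1 symbol stood on more than 1 row. The authors' flag for genes expressed above their baseline covered 13366 genes in NZB/W, 13539 in NZM2410 and 14191 in NZW/BXSB. Median array levels were about 7.02 in non-proteinuric 23-week NZB/W kidneys, 7.14 and 7.17 in prenephritic and nephritic NZM2410 kidneys and 7.70 and 7.74 in those of NZW/BXSB. The median array SD was 1.95, 2.17 and 2.07 in the 3 tables, and no 2 arrays held identical values. Levels are relative, and RMA compresses differences of dim genes, so fold changes near the floor are understated. The median standard error of a fold change was 0.0737, 0.0789, 0.0722 and 0.0803 in the 36-against-16-week, onset, 23-against-16-week and 36-week-against-onset comparisons, 0.0918 in NZM2410 and 0.0720 in NZW/BXSB. The controls on the arrays were used as technical measures: the spiked hybridization and poly-A controls and the 3' minus 5' signal of actin and Gapdh, compared between groups by exact permutation tests, two-sided, with Benjamini-Hochberg adjustment over 30 tests.

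Groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The values were tested as deposited, on the log2 scale and without a filter, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 1 fit of group means per strain table, so that the 4 NZB/W groups shared 1 estimate of the spread. In 6 comparisons, 36 against 16 weeks, onset against non-proteinuric at 23 weeks, 23 against 16 weeks and 36 weeks against onset in NZB/W, and nephritic against prenephritic in NZM2410 and in NZW/BXSB, genes were called at a Benjamini-Hochberg adjusted p under 0.05. Because tables may have been normalized separately, strains were compared only through fold changes from within each table. The difference of 2 strains' fold changes was tested with its summed variance and Satterthwaite degrees of freedom, adjusted over all genes. Overlaps were set against the number that independent lists of the same sizes give. The correlation of onset and late fold changes has a jackknife standard error over the arrays.

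The 33 fixed lists, 15 of pathways and 18 of cell types, held 555 symbols, of which 518 were measured: interferon response, MHC class II antigen presentation, MHC class I antigen processing, complement, chemokines, NF-kB and inflammatory cytokine targets, extracellular matrix and remodelling, tubular injury, cell cycle, oxidative phosphorylation, fatty acid oxidation and peroxisome, citrate cycle, glycolysis and hypoxia, ER stress, sex-linked, mononuclear phagocyte, T cell, B cell, plasma cell and immunoglobulin, neutrophil, dendritic cell, NK and cytotoxic cell, podocyte, mesangial, pericyte and smooth muscle, endothelium, proximal tubule, thick ascending limb, distal convoluted tubule, collecting duct principal cell, intercalated cell, erythroid (blood), adipocyte (perirenal fat) and adrenal cortex. The last 3 stand for blood, fat and adrenal tissue that a kidney sample can carry. Each list was tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and with fry as alternatives. Members were also counted with adjustment over the list alone. Named genes were the 8 largest rises and falls of each comparison among called genes, up to 4 called members of each list by size or, with none, the member with the smallest p, 6 genes in every comparison (Lcn2, Havcr1, C3, Nphs1, Slc34a1 and Umod), the 8 rises and 8 falls largest in all 3 strains, and the 4 clearest differences per pair of strains. Names were left out for length from the end of each ranking, and some genes that the rule names are not reported here.

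Alternatives were the series table, a filter leaving out the dimmest 40 percent of genes (9885 left), quantile normalization, median centring, an intensity trend in the variance, array weights, the title's replicate number as a block, a shared part of the titles as a random block, only the 2 groups compared, 1 fit of all samples for strain differences, an adjusted p under 0.01 for the overlap, and each sample left out in turn. Chosen after the data were seen were the authors' expressed genes, covariates for the hybridization controls, the Gapdh signal and the adrenal cortex list, 16-week replicates 1 to 3 left out together, whose control signals stood apart, samples left out in turn for overlaps and differences, and fold changes scaled by the spread of their table. Genes not on these tables were not analysed here.

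The code was tested on simulated data with 200 of 16475 genes changed. Changes of 0.5, 1 and 2 (log2) were found in 88.1%, 98.5% and 100% of genes for 36 against 16 weeks, 88.1%, 97.0% and 98.5% for onset, 82.1%, 100% and 100% for 23 against 16 weeks, 79.1%, 98.5% and 100% for 36 weeks against onset, 71.6%, 89.6% and 98.5% for NZM2410 and 83.6%, 97.0% and 100% for NZW/BXSB. Of 10 lists shifted by 0.3, 10 were found in each comparison, and of 10 unshifted lists 2 were called in the onset simulation and 0 in the others by camera. Simulated genes were drawn independently of each other and lists at random, so camera was not tested on lists of correlated genes. Of 200 differences of 2 between strains, 199 were found per pair, and smaller differences were not simulated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.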

Results

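Whole-kidney RNA from 3 strains of lupus-prone mice was measured on 57 Affymetrix arrays, 1 per sample. The strains, NZB/W, NZM2410 and NZW/BXSB, develop an autoimmune disease in which immune complexes lodge in the kidney. NZB/W kidneys came in 4 groups, taken at 16 weeks before nephritis (n = 8), at 23 weeks without proteinuria (n = 11), at 23 weeks at proteinuria onset (n = 6) and at 36 weeks with nephritis (n = 10). NZM2410 kidneys were prenephritic (n = 5) or nephritic (n = 5), and NZW/BXSB kidneys were prenephritic (n = 6) or nephritic (n = 6), with no age stated for either strain. The values were log2 expression levels of 16475 genes in each strain. Nothing in the labels states that the arrays came from separate animals, so p-values measure the spread between these samples, and the number of arrays limits the precision. Changes are log2 fold changes ± standard error from limma with adjusted p-values from the Benjamini-Hochberg method, and levels are log2 means ± SD. In counts over a fixed list, members counted as neither rising nor falling did not pass. Immunoglobulin, H2, Cyp2d and Slc22a genes have near-identical relatives that can share probes, so their values are uncertain as to the member measured.

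Nephritic NZB/W kidneys at 36 weeks (n = 10) were compared with prenephritic kidneys at 16 weeks (n = 8), which sets established disease against the young kidney. Lcn2, which encodes an iron-carrier-binding protein released by injured tubules, rose by 4.04 ± 0.49 (adjusted p = 9.23e-07, higher than the 16-week mean in 10 of 10), from a level of 5.98 ± 0.39 to 10.02 ± 1.52. Antibody transcripts rose as far, with Igkc up by 3.96 ± 0.42 and Jchain, the chain that joins IgA and IgM into polymers, up by 3.71 ± 0.40 (adjusted p = 1.62e-07 for each, 10 of 10 samples). The genes that fell furthest included Serpina6, which encodes corticosteroid-binding globulin and fell by 1.98 ± 0.32 (adjusted p = 3.41e-05), and Gatm, an enzyme of creatine synthesis, which fell by 1.89 ± 0.36 (adjusted p = 0.000237), each in 10 of 10 samples. In all, 1813 genes rose and 2525 fell, 211 and 83 of them by 2-fold or more, and 24 of 33 fixed lists were called by camera.

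Markers of mononuclear phagocytes moved as a group, as 24 of 24 rose (24 adjusted over the list alone), with a median change of 1.42 (camera adjusted p = 5.19e-24), led by Ms4a7 (2.40), Lyz2 (2.31) and Cd14 (1.89). Of the class I list 12 of 12 rose (12 adjusted over the list alone), including H2-K1 (1.53) and Psmb8 (1.52). Of the class II list 10 of 12 rose (11 adjusted over the list alone), including the protease gene Ctss (2.31), H2-DMb1 (1.62) and Cd74 (1.61), the invariant chain. Of the complement list 12 of 18 rose and 0 fell (14 and 1 adjusted over the list alone), with the C1q chain genes C1qc (2.56), C1qb (2.55) and C1qa (2.22) and the central component C3 (2.0). Among chemokines 18 of 23 rose and 0 fell (19 and 1 adjusted over the list alone), led by Ccl8 (2.39) and Cxcl13 (2.33), which attracts B cells. Of NF-kB and cytokine targets 21 of 22 rose (21 adjusted over the list alone), led by Socs3 (2.23) and the adhesion gene Icam1 (1.36). Of plasma cell and immunoglobulin genes 11 of 13 rose (11 adjusted over the list alone), with Igkv6-15 (3.63) and Ighm (3.60) beside Igkc and Jchain. These 7 lists were also called when the correlation between genes was estimated (adjusted p = 0.0470 for each with an estimated correlation). Over all 6 comparisons, that estimate gave the highest adjusted p of any alternative for 105 of 111 called lists.

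10 other lists were called up by camera, and each call was lost with an estimated correlation, while fry called 9 of them, all but neutrophils (adjusted p = 0.0718). Of interferon response genes 21 of 26 rose (23 adjusted over the list alone), with Oasl2 (1.53) and Ifit1 (1.41). Of matrix and remodelling genes 24 of 32 rose and 1 fell (26 and 1 adjusted over the list alone), with Tgfbi (1.90) and Timp1 (1.33). Of tubular injury genes 25 of 26 rose (25 adjusted over the list alone), including Havcr1, the kidney injury molecule, by 1.15 ± 0.27 (adjusted p = 0.00196), Cd44 (2.01) and the fibrinogen chain Fgg (1.93). Of cell cycle genes 15 of 24 rose (17 adjusted over the list alone), with Cdc20 (1.10) and Mki67 (1.01). The calls of these 4 lists were lost with adjusted p = 0.0787, 0.0704, 0.0582 and 0.197 with an estimated correlation. Among lymphocyte markers 13 of 18 rose (15 adjusted over the list alone) for T cells, with Cd3g (1.36) and Cd3d (1.01), and 10 of 13 rose (12 adjusted over the list alone) for B cells, with Cd72 (1.77) and Cd79b (1.70). For NK and cytotoxic cells 6 of 12 rose (6 adjusted over the list alone), for dendritic cells 4 of 11 rose (5 adjusted over the list alone) and for neutrophils 3 of 11 rose (3 adjusted over the list alone). With an estimated correlation these 5 had adjusted p = 0.119, 0.0787, 0.285, 0.190 and 0.416. Of ER stress genes 5 of 17 rose and 2 fell (5 and 2 adjusted over the list alone), with Asns (0.78) up and Herpud1 (-0.57) down (adjusted p = 0.278 with an estimated correlation). Herpud1 had an adjusted p of 0.000176 to 0.250 over its alternatives and of 0.0541 after quantile normalization. The neutrophil call was lost without 36-week replicates 3 (0.0638) and 5 (0.0699), and the ER stress call without 16-week replicate 3 (0.126) and 36-week replicates 3 (0.0663) and 10 (0.0501), as adjusted p in brackets.

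7 lists were called down by camera, and each call was lost with an estimated correlation. Of oxidative phosphorylation genes 26 of 27 fell (26 adjusted over the list alone), median -0.46, with Ndufs1 (-0.62) and Ndufa9 (-0.59). Of citrate cycle genes 17 of 17 fell (17 adjusted over the list alone), with Idh3b (-0.66) and Idh3a (-0.64). Of fatty acid oxidation genes 13 of 27 fell (14 adjusted over the list alone), led by Ppargc1a (-1.10), a coactivator of mitochondrial genes. Of proximal tubule markers 21 of 25 fell (22 adjusted over the list alone), median -0.78, with Slc6a19 (-1.5) and Slc5a2 (-1.34) and the phosphate transporter Slc34a1 (-1.05 ± 0.23, adjusted p = 0.000949). Of distal convoluted tubule markers 6 of 6 fell (6 adjusted over the list alone), with Pvalb (-1.85), Calb1 (-1.40) and Slc8a1 (-0.97). Of thick ascending limb markers 6 of 10 fell (6 adjusted over the list alone), with Egf (-1.22) and Ptger3 (-0.84). Of intercalated cell markers 4 of 8 fell (5 adjusted over the list alone). That estimate gave adjusted p = 0.119, 0.119, 0.341, 0.137, 0.0787, 0.248 and 0.335 for these 7 lists, in that order. Further falls outside these lists or their calls were Dnase1 (-1.94), Slc22a29 (-1.75), the water channel Aqp4 (-1.72) and Lpar3 (-1.66). Umod, the thick ascending limb gene for uromodulin, fell by 0.23 ± 0.08 (adjusted p = 0.0296), with 0.00159 to 0.991 over its alternatives. Quantile normalization turned that fall into a change of 0.000866, and it was also lost on leaving out 16-week replicates 4 (0.0867), 6 (0.0530), 7 (0.0515) and 8 (0.0521) and 36-week replicates 3 (0.0561), 4 (0.0660) and 5 (0.0720).

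The 9 remaining lists were not called. Of podocyte markers 1 of 14 rose and 1 fell (1 and 1 adjusted over the list alone), with Magi2 at -0.53, while Nphs1, the slit diaphragm protein nephrin, had a change of -0.16 ± 0.14 (adjusted p = 0.435). Of mesangial, pericyte and smooth muscle markers 4 of 10 rose and 2 fell (4 and 2 adjusted over the list alone). Of endothelial markers 3 of 14 rose and 1 fell (3 and 1 adjusted over the list alone). Of collecting duct principal cell markers 1 of 9 fell (1 adjusted over the list alone). Of glycolysis and hypoxia genes 1 of 13 fell (1 adjusted over the list alone), its median below 0 (-0.02) and its test pointing up. Of sex-linked genes 0 of 4 passed (0 adjusted over the list alone). Of erythroid genes 1 of 5 rose (1 adjusted over the list alone), Alas2 by 1.60. Of adipocyte genes 0 of 7 passed (0 adjusted over the list alone). Of adrenal cortex genes 0 of 8 passed (0 adjusted over the list alone). The signal of the Gapdh control at the 3' end minus that at the 5' end, a measure of RNA integrity, was 0.204 ± 0.192 at 36 weeks and 0.0152 ± 0.0961 at 16 weeks (exact permutation test, two-sided, p = 0.0220, 0.165 adjusted over 30 tests). With it as a covariate, chosen after the data were seen, 2527 genes were called, of which 2295 were among the 4338, and Dnase1, Mki67, Alas2, Herpud1 and Umod lost their calls, at adjusted p = 0.0559, 0.236, 0.119, 0.250 and 0.226. The count was 6542 with array weights and 2731 with the title stem, a part of the title that some samples share, as a random block. Age and stage differ together in this comparison.

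At 23 weeks, NZB/W kidneys at proteinuria onset (n = 6) were set against kidneys of the same age without proteinuria (n = 11). Lcn2 was the gene that rose furthest, by 2.25 ± 0.53 (adjusted p = 0.0174, 6 of 6 samples above the non-proteinuric mean). Cdc20, an activator of the anaphase-promoting complex, rose by 1.68 ± 0.23 (adjusted p = 0.000116), C1qb by 1.55 ± 0.33 (adjusted p = 0.00790), the interferon-inducible Ifi202b by 1.55 ± 0.34, the lectin gene Clec4a3 by 1.69 ± 0.41 and Ctss by 1.48 ± 0.28, each in 6 of 6 samples. Falls were smaller, with A1cf down by -0.78, Slc16a14 by -0.73, Pdzrn4 by -0.50, the nuclear receptor gene Esrrb by -0.50 and the magnesium channel Trpm6 by -0.49. Of 345 genes called, 281 rose and 64 fell, and 35 rose by 2-fold or more. The rising share, 81.4%, was 64.8% after quantile normalization.

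At onset 10 lists in which members passed were called up by camera, and each call was lost with an estimated correlation. Of cell cycle genes 15 of 24 rose (20 adjusted over the list alone), median 0.50 (camera adjusted p = 8.55e-22), with Rrm2 (1.29) and Mki67 (1.10) beside Cdc20. Of phagocyte markers 10 of 24 rose (22 adjusted over the list alone), median 0.79, with Ms4a7 (1.33), Lyz2 (1.31) and Tyrobp (1.16). Of matrix genes 4 of 32 rose (17 adjusted over the list alone), with Col3a1 (1.43), Vim (1.32) and Tgfbi (1.28). Of complement genes 5 of 18 rose (12 adjusted over the list alone), with C1qc (1.28) beside C1qb. Of interferon response genes 6 of 26 rose (14 adjusted over the list alone), with Ifit1 (1.11) and Bst2 (0.71). Of the class I list 3 of 12 rose (7 adjusted over the list alone), with H2-K1 (0.77) and B2m (0.60). Of the class II list 1 of 12 rose (6 adjusted over the list alone), which was Ctss. Of tubular injury genes 7 of 26 rose and 0 fell (10 and 1 adjusted over the list alone), with Cd44 (1.17) beside Lcn2. Of NF-kB and cytokine targets 4 of 22 rose (10 adjusted over the list alone), with Socs3 (1.17) and Icam1 (0.80). Of chemokines 2 of 23 rose (5 adjusted over the list alone), with Cxcl10 (1.0). For these 10 lists that estimate gave higher values (adjusted p = 0.135, 0.135, 0.135, 0.135, 0.203, 0.171, 0.203, 0.203, 0.203 and 0.203, in that order). Outside these lists, the podocyte gene Synpo rose by 0.37 and the respiratory chain assembly gene Cox10 fell by 0.22 ± 0.06, though neither list was called.

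Of distal convoluted tubule markers 1 of 6 fell (3 adjusted over the list alone), which was Trpm6, median -0.50. Of proximal tubule markers 0 of 25 passed (0 adjusted over the list alone), median -0.21. Both lists were called down (camera adjusted p = 0.00402 and 0.0352), and the calls were lost with adjusted p = 0.246 and 0.895, in that order, with an estimated correlation. 3 lists with no single call rose by camera, mesangial, pericyte and smooth muscle markers (median 0.14), plasma cell and immunoglobulin genes (0.26) and endothelial markers (0.06), with adjusted p = 0.246, 0.529 and 0.529, in that order, with an estimated correlation. The proximal tubule call was lost without non-proteinuric 23-week replicates 3 (0.0528), 6 (0.0507), 9 (0.0588) and 10 (0.0706) and onset replicate 5 (0.784), the last with its direction turned. The endothelial call was lost without non-proteinuric 23-week replicates 1 (0.103), 2 (0.0791), 3 (0.0826) and 4 (0.0555) and onset replicates 2 (0.0649), 4 (0.0670) and 6 (0.189). The plasma cell call was lost without onset replicate 4 (0.0638), as adjusted p in brackets. The change of Slc34a1 was -0.28 ± 0.25 (adjusted p = 0.527), that of Havcr1 0.49 ± 0.29 (0.352), that of C3 0.85 ± 0.29 (0.117), that of Nphs1 -0.10 ± 0.15 (0.727) and that of Umod 0.14 ± 0.09 (0.356), so none of these 5 passed.

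The spiked hybridization controls, which carry no kidney RNA, were brighter on the onset arrays, 9.67 ± 0.19 (lowest 9.49) against 9.0 ± 0.19 (highest 9.30) (exact permutation test, two-sided, p = 8.08e-05, 0.00242 adjusted over 30 tests). The 3' minus 5' Gapdh signal was 0.108 against -0.00830 (exact p = 0.0115, adjusted 0.115). The count of 345 was 109 with these controls as a covariate, 189 with the Gapdh signal and 209 with the adrenal cortex score, all chosen after the data were seen. It was 2167 with array weights, 1141 with only the 2 groups and 216 with the title stem as a random block. It was 39, 173 and 186 without onset replicates 5, 3 and 4, and 229, 195, 213 and 214 without non-proteinuric replicates 6, 7, 8 and 9. Of the 30 named genes that passed, 7 (Cdc20, Ctss, Esrrb, B2m, Vim, Tgfbi and Rrm2) passed with any 1 sample left out. Calls lost were 4, 3, 14, 16, 23 and 1 of 30 without onset replicates 1 to 6. Without non-proteinuric replicates 1 to 11 they were 3, 4, 1, 8, 5, 5, 9, 8, 8, 5 and 4. Quantile normalization put the adjusted p of Col3a1 at 0.0578 and of Mki67 at 0.0520, within ranges over all alternatives of 0.000449 to 0.178 and 0.000188 to 0.289.

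Before proteinuria, 23-week NZB/W kidneys (n = 11) were compared with 16-week kidneys (n = 8). The genes that passed were antibody genes. Igkc rose by 2.93 ± 0.41 (adjusted p = 0.000460), from 9.93 ± 1.24 to 12.86 ± 0.83, Jchain by 2.34 ± 0.39 (adjusted p = 0.00808) and Igha, the IgA heavy chain, by 1.96 ± 0.35 (adjusted p = 0.0145), each above the 16-week mean in 11 of 11 samples. Injury genes did not pass, with Lcn2 at 0.09 ± 0.48 (adjusted p = 0.981), Havcr1 at 0.15 ± 0.27 (0.927), C3 at 0.36 ± 0.27 (0.820), Nphs1 at 0.17 ± 0.14 (0.828), Slc34a1 at -0.03 ± 0.23 (0.987) and Umod at -0.11 ± 0.08 (0.820). The 3 genes were called by limma, with 0 falling and 963 genes in both directions at an unadjusted p under 0.05. The count was 3697 with array weights, 19 with only the 2 groups and 33, of which 17 fell, without 16-week replicates 1 to 3, chosen after the data were seen. In 16-week replicate 1 Igkc was at 12.90 (mean 9.50 in the other 7), and Jchain and Igha were also above the others. Over the alternatives the adjusted p ranged from 4.03e-07 to 1.0 for Igkc, 0.000165 to 1.0 for Jchain and 0.000183 to 1.0 for Igha, highest with the title stem as a random block, where 0 genes were called. Igha was lost without 16-week replicates 2 (0.0510), 4 (0.0610) and 6 (0.0712), and the count was 5 without 16-week replicate 3.

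Of plasma cell and immunoglobulin genes 2 of 13 rose (4 adjusted over the list alone), and the list was called up (camera adjusted p = 5.50e-06, median 0.09). Adrenal cortex markers, with a median change of 1.55, and adipocyte markers, with 0.48, were also called up, though of the first 0 of 8 passed (0 adjusted over the list alone) and of the second 0 of 7 passed (2 rose adjusted over the list alone). Mc2r, the corticotropin receptor, was at 0.81 ± 0.30 (adjusted p = 0.820) and Lipe at 0.48 ± 0.15 (0.820). The mean level of the adrenal list was 8.07 ± 2.05 at 23 weeks and 6.78 ± 0.43 at 16 weeks. Mesangial, pericyte and smooth muscle markers (median 0.17), endothelial (0.09), matrix (0.14), B cell (0.10) and T cell (0.09) lists were called up and oxidative phosphorylation (-0.11) down. With an estimated correlation all 9 calls were lost (adjusted p = 0.499, 0.499, 0.315, 0.315, 0.927, 0.927, 0.927, 0.927 and 0.927, in that order), and fry called 0 lists, its lowest unadjusted p being 0.00484. Lost calls, with adjusted p in brackets, were B cell without 16-week replicate 8 (0.0602) and non-proteinuric 23-week replicates 1 (0.0508), 3 (0.0642), 4 (0.0684) and 8 (0.0529). T cell was lost without 16-week replicate 6 (0.0566) and non-proteinuric 23-week replicates 4 (0.0610) and 8 (0.0529), and endothelium without 16-week replicate 2 (0.228) and non-proteinuric 23-week replicate 10 (0.0674). The hybridization controls were at 9.43 ± 0.35 at 16 weeks and 9.0 ± 0.19 at 23 weeks (exact permutation test, two-sided, p = 0.000304, adjusted 0.00456). With them as a covariate, chosen after the data were seen, 1 gene was called, with Jchain at an adjusted p of 0.0560 and Igha at 0.290. That covariate turned the direction of the matrix list (adjusted p = 0.983, range over its alternatives 8.95e-06 to 0.983) and of the oxidative phosphorylation list (0.276, range 1.35e-08 to 0.935).

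Nephritic NZB/W kidneys at 36 weeks (n = 10) were compared with kidneys at proteinuria onset (n = 6). Ubd, an interferon-inducible ubiquitin-like gene, rose by 1.64 ± 0.36 (adjusted p = 0.0193, 9 of 10 samples), Cxcl13 by 1.35 ± 0.32 (8 of 10), Cyp2d9 by 1.22 ± 0.34 (10 of 10), the guanylate-binding gene Gbp8 by 1.17 ± 0.28 (10 of 10) and H2-DMb1 by 1.03 ± 0.26 (10 of 10). Car3, a carbonic anhydrase abundant in fat, fell by 1.81 ± 0.47, Gatm fell by 1.54 ± 0.39, Apob fell by 1.29 ± 0.34, Cela1 fell by 1.23 ± 0.20 (adjusted p = 0.00478) and Lpar3 fell by 1.11 ± 0.24. In all, 94 genes rose and 288 fell, and camera called 25 lists, 0 of them with an estimated correlation. Lcn2, with 1.70 ± 0.54 (adjusted p = 0.0742), did not pass, nor did Havcr1 (0.52 ± 0.30, 0.281), C3 (0.79 ± 0.30, 0.115), Nphs1 (-0.23 ± 0.15, 0.344), Slc34a1 (-0.75 ± 0.25, 0.0875) or Umod (-0.27 ± 0.09, 0.0844).

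T cell markers were called up as a list, as 2 of 18 rose (15 adjusted over the list alone), with Lck (0.53) and Cd2 (0.50). Of the class II list 3 of 12 rose (8 adjusted over the list alone), with H2-DMb2 (0.81). Called up as well were MHC class I, chemokines, NF-kB targets, interferon response, complement, tubular injury, phagocytes, B cells, plasma cells, NK cells, dendritic cells, neutrophils and erythroid genes, with 1, 3, 0, 0, 0, 2, 0, 1, 0, 1, 1, 1 and 0 members rising and 7, 6, 6, 5, 5, 4, 1, 3, 4, 7, 2, 2 and 2 adjusted over the list alone. These 15 calls were lost with adjusted p = 0.241 or 0.246 (0.418 for neutrophils) with an estimated correlation. Of oxidative phosphorylation genes 5 of 27 fell (22 adjusted over the list alone), with Cyc1 (-0.48) and Ndufa9 (-0.47). Of citrate cycle genes 7 of 17 fell (14 adjusted over the list alone), with Idh3b (-0.52) and Sucla2 (-0.50). Of fatty acid oxidation genes 1 of 27 fell (6 adjusted over the list alone), which was Ppargc1a (-0.96). Of proximal tubule markers 2 of 25 fell (12 adjusted over the list alone), which were Gatm and Slc5a2 (-0.92). Of mesangial and smooth muscle markers 2 of 10 fell (2 adjusted over the list alone), which were Myh11 (-0.74) and Itga8 (-0.71). Of endothelial markers 3 of 14 fell (3 adjusted over the list alone). Of podocyte markers 1 of 14 fell (5 adjusted over the list alone). Of distal convoluted tubule markers 0 of 6 passed (2 fell adjusted over the list alone). Adipocyte markers (median -0.72, 6 of 7 falling adjusted over the list alone), and adrenal cortex markers (median -1.17, 0 of 8 passing), were called down beside these. The 10 falling calls were lost with adjusted p = 0.241 or 0.246 (0.463 for adrenal cortex) with an estimated correlation. Lost calls, with adjusted p in brackets, were adrenal cortex without onset replicates 1 (0.280) and 3 (0.0643) and 36-week replicates 1 (0.0801) and 7 (0.0504). Complement was lost without onset replicate 2 (0.0630) and neutrophils without onset replicates 4 (0.0618) and 6 (0.0682) and 36-week replicates 3 (0.101), 5 (0.0762) and 8 (0.0519).

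The counts of this comparison rested on single samples. Without onset replicate 5, 2008 genes were called, and without onset replicates 1, 2, 3, 4 and 6 the counts were 48, 19, 94, 121 and 60. They were 96, 93, 957 and 791 without 36-week replicates 4, 5, 9 and 10, 205 after quantile normalization, and, with covariates chosen after the data were seen, 8 with the hybridization controls, 110 with the Gapdh signal and 35 with the adrenal cortex score. With only the 2 groups in the fit, limma called 1 gene, with array weights 2352 and with the title stem as a random block 122. Of the 21 named genes that passed, 2 (Cela1 and Myh11) passed with any 1 sample left out. Quantile normalization ended the calls of Apob, Car3, Cd2, Cyc1, Cyp2d9, Gatm, Lck, Slc5a2 and Sucla2, with adjusted p from 0.0511 to 0.0769. Calls lost were 19, 19, 14, 11 and 17 without onset replicates 1, 2, 3, 4 and 6, and 3, 2, 3, 13, 12, 4 and 1 without 36-week replicates 1 to 7. In onset replicate 5, the levels of Lpar3 (6.52), Ppargc1a (9.40), Cyc1 (12.44) and Idh3b (11.20) lay below those of the other 5 onset samples.

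**Figure D1:**
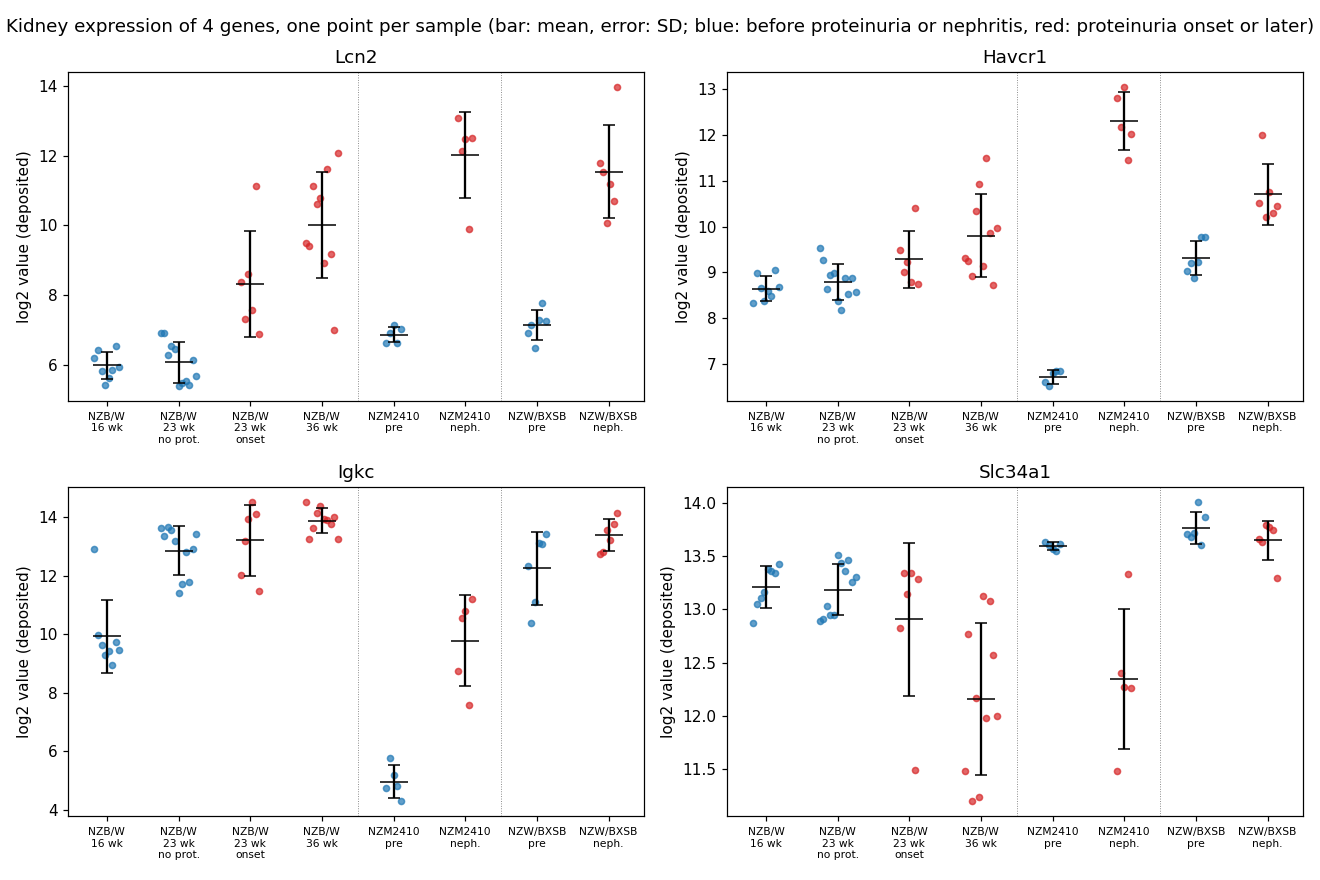
Log2 expression level (vertical axis) of Lcn2, Havcr1, Igkc and Slc34a1 in each of 57 kidney samples, in 8 groups along the horizontal axis. Each point is 1 sample, the bar the group mean and the error bar the SD, in blue before proteinuria or nephritis and in red from proteinuria onset on. Mean Lcn2 is 5.98 at 16 weeks, 6.06 and 8.32 at 23 weeks without and with proteinuria and 10.02 at 36 weeks, while Havcr1 goes from 6.73 to 12.31 in NZM2410 and from 9.31 to 10.71 in NZW/BXSB.

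In NZM2410 mice, an inbred strain derived from NZB and NZW parents, nephritic kidneys (n = 5) were compared with prenephritic kidneys (n = 5). Havcr1 rose by 5.58 ± 0.25 (adjusted p = 5.05e-07), from 6.73 ± 0.15 to 12.31 ± 0.64, and Lcn2 by 5.16 ± 0.46 (adjusted p = 7.72e-05), each in 5 of 5 samples. Igkc rose by 4.83 ± 0.60, Jchain by 3.81 ± 0.58, the epithelial keratin gene Krt20 by 3.74 ± 0.41, Cd44 by 3.69 ± 0.35 and C3 by 2.87 ± 0.47. Serpina6 fell by 5.03 ± 0.42 (adjusted p = 5.66e-05), the endonuclease gene Dnase1 fell by 3.55 ± 0.40, Pvalb fell by 3.20 ± 0.55, the tyrosine-degrading Hpd fell by 2.83 ± 0.32 and the phosphate transporter Slc34a3 fell by 2.71 ± 0.40, all in 5 of 5 samples. Of the 4161 genes called, 1884 rose, 316 by 2-fold or more, and 2277 fell, 169 by 2-fold or more. With array weights 6449 were called.

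Of tubular injury genes 25 of 26 rose (25 adjusted over the list alone), median 1.79 (camera adjusted p = 4.25e-20). Of phagocyte markers 22 of 24 rose (23 adjusted over the list alone), with Cd14 (3.12) and Cd68 (2.24). Of the class I list 12 of 12 rose (12 adjusted over the list alone), with H2-K1 (2.36) and Psmb8 (1.95). Of the class II list 9 of 12 rose (10 adjusted over the list alone), with H2-DMb2 (2.58) and H2-Ab1 (2.54). Of interferon response genes 21 of 26 rose (22 adjusted over the list alone), with Oasl2 (1.82) and Ifit1 (1.73). Among chemokines 15 of 23 rose and 0 fell (17 and 1 adjusted over the list alone), with Ccl5 (2.92) and Cxcl1 (2.41). Of NF-kB and cytokine targets 16 of 22 rose (18 adjusted over the list alone), with Vcam1 (3.22) and Socs3 (2.86). Of complement genes 11 of 18 rose and 2 fell (12 and 2 adjusted over the list alone). Of matrix genes 11 of 32 rose and 1 fell (12 and 2 adjusted over the list alone), with Timp1 (2.26). Of cell cycle genes 19 of 24 rose and 1 fell (21 and 1 adjusted over the list alone), with Birc5 (0.98). Of ER stress genes 7 of 17 rose (10 adjusted over the list alone), with Asns (1.23) and Xbp1 (0.76). Of T cell markers 4 of 18 rose (4 adjusted over the list alone). Of plasma cell genes 6 of 13 rose and 1 fell (6 and 1 adjusted over the list alone). These 13 lists were called up by camera, and their calls were lost with adjusted p = 0.184, 0.184, 0.206, 0.206, 0.206, 0.184, 0.184, 0.184, 0.452, 0.184, 0.245, 0.512 and 0.353, in that order, with an estimated correlation.

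Of oxidative phosphorylation genes 24 of 27 fell (27 adjusted over the list alone), with Ndufs1 (-0.79) and Cycs (-0.66). Of citrate cycle genes 16 of 17 fell (17 adjusted over the list alone), with Pcx (-1.11) and Idh3b (-0.66). Of fatty acid oxidation genes 10 of 27 fell (11 adjusted over the list alone). Of proximal tubule markers 1 of 25 rose and 20 fell (1 and 24 adjusted over the list alone), with Gatm (-1.85) and Slc34a1 (-1.24 ± 0.25, adjusted p = 0.00315) falling and Cyp4b1 (1.80) rising. Of distal convoluted tubule markers 4 of 6 fell (5 adjusted over the list alone), with Calb1 (-1.85) beside Pvalb. Podocyte markers fell in part, 1 of 14 rose and 7 fell (1 and 7 adjusted over the list alone): Nphs1 fell by 0.65 ± 0.11 (adjusted p = 0.00116, 5 of 5 samples) and the transcription factor gene Tcf21 fell by 0.89 ± 0.27, while Cd2ap rose by 1.04 ± 0.16. Of endothelial markers 8 of 14 fell (9 adjusted over the list alone), with Emcn (-0.95) and Tek (-0.78). These 7 lists were called down, and their calls were lost with adjusted p = 0.216, 0.206, 0.609, 0.206, 0.206, 0.207 and 0.433, in that order, with an estimated correlation. Umod had a change of 0.17 ± 0.07 (adjusted p = 0.0929). Emcn was lost without prenephritic replicates 1 (0.0590), 2 (0.0578) and 3 (0.0534) and nephritic replicate 3 (0.0572). Tcf21 was lost without prenephritic replicates 1 (0.0746) and 2 (0.0705) and nephritic replicate 3 (0.0748). Tek was lost without prenephritic replicates 1 (0.0574), 2 (0.0602) and 3 (0.0597) and nephritic replicates 2 (0.0540) and 3 (0.0672), with adjusted p in brackets. The fatty acid oxidation call was lost without nephritic replicate 2 (0.134) and after quantile normalization, at an adjusted p of 0.106.

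In NZW/BXSB mice, nephritic kidneys (n = 6) were compared with prenephritic kidneys (n = 6). Lcn2 rose by 4.40 ± 0.50 (adjusted p = 0.000317), the fibrillar collagen genes Col3a1 by 2.73 ± 0.24 (adjusted p = 8.76e-05) and Col1a1 by 2.45 ± 0.31, Serpina10 by 2.62 ± 0.25, C3 by 2.43 ± 0.37, and Timp1, an inhibitor of matrix-degrading enzymes, by 2.42 ± 0.25, each in 6 of 6 samples. Cyp2d12 fell by 3.12 ± 0.43, Hpd fell by 2.74 ± 0.48, the heat shock gene Hspa1a fell by 2.61 ± 0.59 and Dnase1 fell by 2.40 ± 0.62, each in 6 of 6 samples. Of 3319 genes called, 1880 rose and 1439 fell, 184 and 58 by 2-fold or more, and 5898 were called with array weights. The rising share, 56.6%, was 38.5% with each array centred on its median. Havcr1 rose by 1.39 ± 0.27 (adjusted p = 0.00398), while Slc34a1 at -0.12 ± 0.09 (adjusted p = 0.387) and Umod at 0.01 ± 0.04 (0.913) did not pass.

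Of matrix genes 25 of 32 rose and 0 fell (25 and 1 adjusted over the list alone), median 0.99 (camera adjusted p = 7.80e-18). Of cell cycle genes 22 of 24 rose (24 adjusted over the list alone), median 1.23, with Rrm2 (1.91) and Cdc20 (1.87). Of phagocyte markers 22 of 24 rose (24 adjusted over the list alone), with Ccr2 (1.63) and Cd14 (1.56). Of tubular injury genes 20 of 26 rose and 1 fell (22 and 1 adjusted over the list alone), with Cd44 (2.04). Of the class I list 12 of 12 rose (12 adjusted over the list alone), with Psmb8 (1.0) and H2-K1 (0.98). Of the class II list 8 of 12 rose (10 adjusted over the list alone), with Ctss (1.27) and H2-DMa (1.03). Of interferon response genes 15 of 26 rose (19 adjusted over the list alone), with Oasl2 (1.42) and Irf7 (1.19). Of complement genes 13 of 18 rose (13 adjusted over the list alone). Of NF-kB and cytokine targets 13 of 22 rose (16 adjusted over the list alone), with Vcam1 (1.63) and Socs3 (1.47). Of chemokines 11 of 23 rose and 1 fell (17 and 1 adjusted over the list alone). Of mesangial, pericyte and smooth muscle markers 4 of 10 rose (4 adjusted over the list alone), with Tagln (0.95) and Pdgfrb (0.62). Of plasma cell genes 3 of 13 rose (3 adjusted over the list alone). These 12 lists were called up, and their calls were lost with adjusted p = 0.106, 0.238, 0.183, 0.183, 0.183, 0.183, 0.352, 0.106, 0.183, 0.183, 0.201 and 0.422, in that order, with an estimated correlation. Of fatty acid oxidation genes 21 of 27 fell (22 adjusted over the list alone), with Acaa2 (-0.96). Of citrate cycle genes 13 of 17 fell (13 adjusted over the list alone), with Pcx (-0.79). Of oxidative phosphorylation genes 11 of 27 fell (13 adjusted over the list alone), with Cycs (-0.41) and Sdha (-0.35). Of proximal tubule markers 8 of 25 fell (12 adjusted over the list alone), with the transporter Slc22a7 (-1.79) and Pck1 (-1.54), a gene of glucose synthesis. Of distal convoluted tubule markers 4 of 6 fell (6 adjusted over the list alone), with Pvalb (-2.22) and Calb1 (-0.97). Of intercalated cell markers 4 of 8 fell (5 adjusted over the list alone). These 6 lists were called down, and their calls were lost with adjusted p = 0.183, 0.222, 0.428, 0.201, 0.183 and 0.271, in that order, with an estimated correlation. The oxidative phosphorylation call was also lost after quantile normalization, at an adjusted p of 0.215.

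Podocyte markers in NZW/BXSB went both ways, 2 of 14 rose and 2 fell (2 and 2 adjusted over the list alone), and the list was not called. Nphs1 fell by 0.32 ± 0.11 (adjusted p = 0.0499, 5 of 6 samples), and Cd2ap and the matrix gene Npnt rose by 0.47 and 0.36. Nphs1 was lost without prenephritic replicates 1 (0.0888), 2 (0.113), 3 (0.0890), 4 (0.0767) and 5 (0.0657) and nephritic replicates 1 (0.0987), 2 (0.106), 3 (0.0939) and 4 (0.0947). Cycs, for cytochrome c, was lost without prenephritic replicates 1 (0.0597), 2 (0.0660), 3 (0.0747), 4 (0.0710) and 6 (0.0589) and nephritic replicates 1 (0.0750), 2 (0.0542), 5 (0.0527) and 6 (0.0653). Npnt was lost without prenephritic replicates 1 (0.0535), 2 (0.0542) and 3 (0.0527), with adjusted p in brackets.

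**Figure D2:**
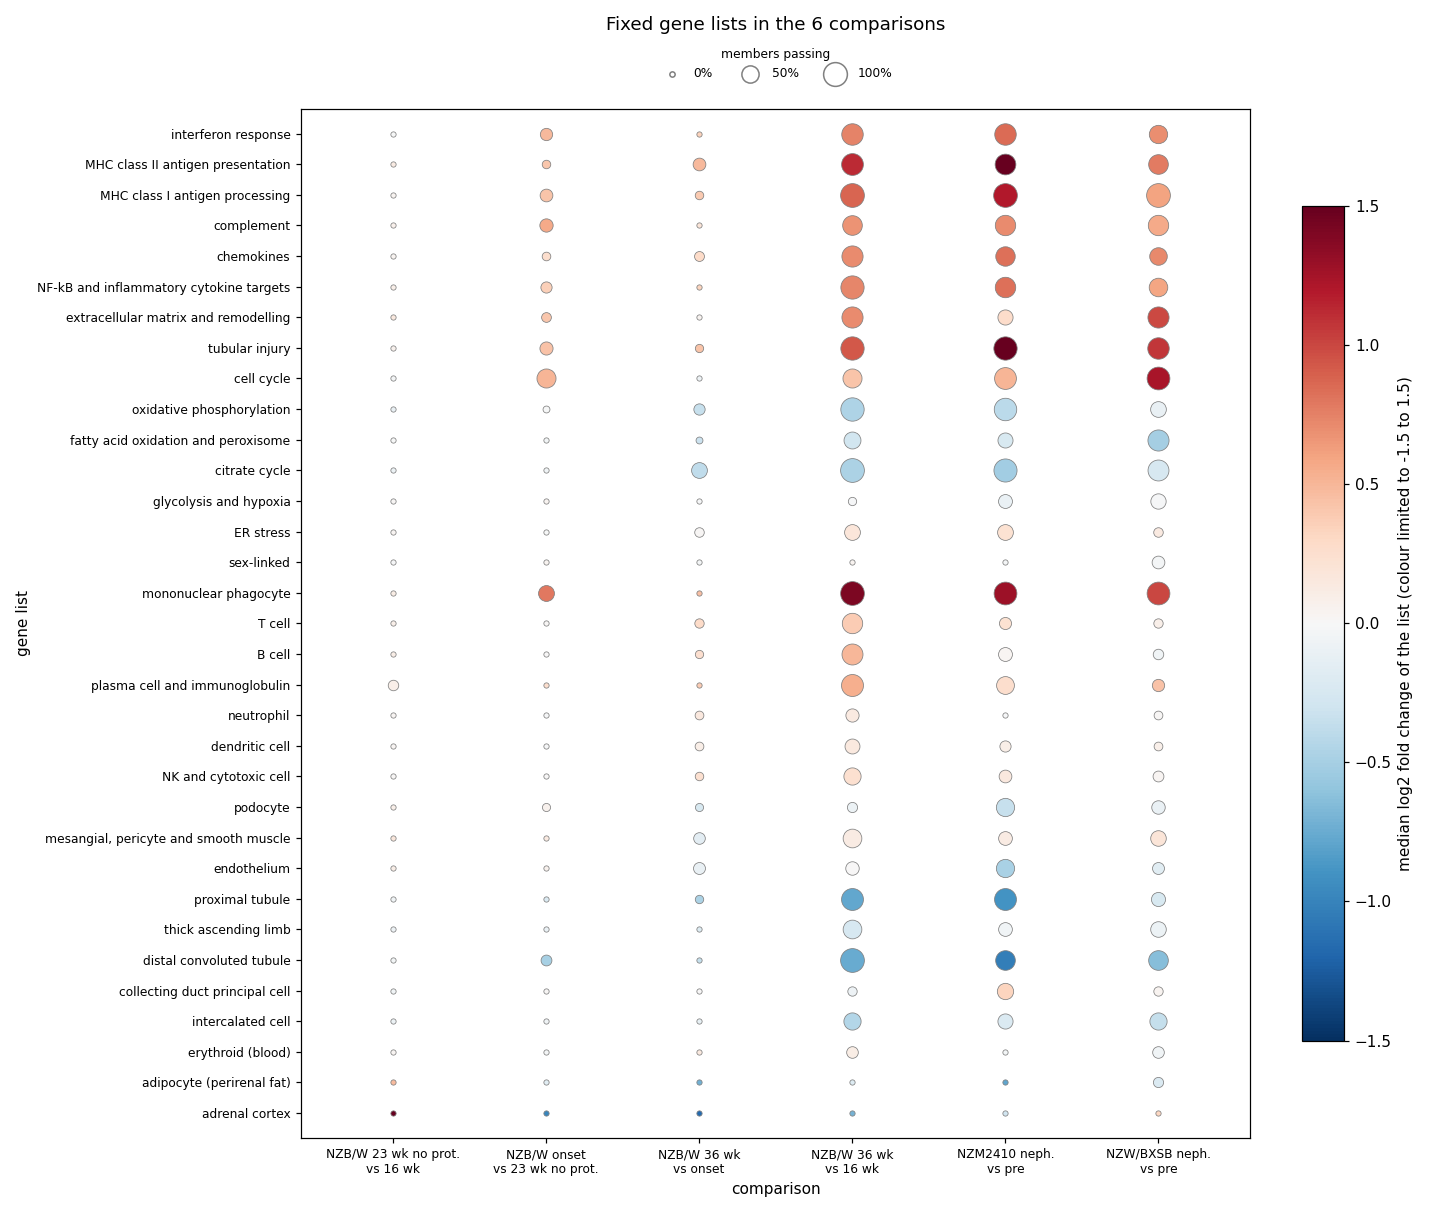
Median log2 fold change (colour, limited to 1.5 either way) of 33 fixed gene lists (vertical axis) in 6 comparisons (horizontal axis); the size of a circle is the share of the list's measured members that passed. Phagocyte markers have medians of 0.11 at 23 against 16 weeks, 0.79 at onset against 23 weeks without proteinuria, 0.45 at 36 weeks against onset, and 1.42, 1.28 and 1.01 in the late NZB/W, NZM2410 and NZW/BXSB comparisons.

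The late NZB/W comparison and the NZM2410 and NZW/BXSB comparisons were then set side by side to find the changes they had in common. Age goes with stage in NZB/W, and titles call the prenephritic NZM2410 samples Young. Effects of age and nephritis are therefore not separated there. In all 3 comparisons, 700 genes rose and 543 fell, against 23.7 and 30.5 for independent lists of these sizes. Called in all 3 with differing signs were 16. Ranked by the smallest of the 3 changes, Lcn2 led the rises, by 4.04, 5.16 and 4.40 in NZB/W, NZM2410 and NZW/BXSB, followed by Cd44 (2.01, 3.69 and 2.04), C3 (2.0, 2.87 and 2.43), Ms4a6b (2.63, 2.64 and 1.77) and Serpina10 (1.69, 2.87 and 2.62). Dnase1 (-1.94, -3.55 and -2.40), Pvalb (-1.85, -3.20 and -2.22), the methyltransferase gene Bhmt (-1.63, -2.36 and -2.39), Hpd (-1.56, -2.83 and -2.74) and Cndp1 (-1.34, -2.26 and -1.19) fell in each. All 12 class I genes rose in the 3 strains, as did 21 of 24 phagocyte markers, 20 of 26 tubular injury genes, 15 of 26 interferon response genes, 13 of 24 cell cycle genes, 13 of 22 NF-kB targets, 9 of 18 complement genes and 6 of 12 class II genes. Of citrate cycle genes 12 of 17 fell in all 3, and of oxidative phosphorylation genes 11 of 27. At an adjusted p under 0.01 the 1243 shared genes were 518. Across genes, which are not independent replicates, Pearson correlations of the fold changes were 0.752 between NZB/W and NZM2410, 0.631 between NZB/W and NZW/BXSB and 0.642 between NZM2410 and NZW/BXSB.

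The size of the change was tested between strains, as the first strain's fold change minus the second's. Between NZB/W and NZM2410, 283 genes differed. Havcr1 differed most clearly (-4.43 ± 0.37, adjusted p = 1.55e-10), rising by 1.15 in NZB/W and 5.58 in NZM2410. Next came Gstt1 (-1.0 ± 0.11, adjusted p = 2.37e-07), the complement regulator Cfi (-1.36 ± 0.19, adjusted p = 8.85e-05) and Ankrd6 (-0.94 ± 0.13, adjusted p = 8.85e-05). Between NZB/W and NZW/BXSB, 951 genes differed, led by Cyp2d9 (3.05 ± 0.38, adjusted p = 3.10e-06), which rose by 1.42 in NZB/W and fell by 1.63 in NZW/BXSB. Next were Npl (-1.64 ± 0.21, adjusted p = 1.12e-05), Pla2g5 (-1.06 ± 0.14, adjusted p = 1.95e-05) and Pcdh7 (-0.84 ± 0.12, adjusted p = 0.000192). Between NZM2410 and NZW/BXSB, 911 differed, led by Havcr1 (4.19 ± 0.37, adjusted p = 3.60e-07), Cyp2d9 (2.77 ± 0.28, adjusted p = 4.74e-06), Kcne1l (-1.59 ± 0.15, adjusted p = 4.83e-06) and Aldh1a1 (1.77 ± 0.21, adjusted p = 4.13e-05). The fall of Slc34a1 was smaller in NZW/BXSB than in NZB/W (-0.94 ± 0.25, adjusted p = 0.0212) and NZM2410 (-1.13 ± 0.26, adjusted p = 0.0225). The rise of Cd44 was larger in NZM2410 than in NZB/W (-1.68 ± 0.43, adjusted p = 0.0411) and NZW/BXSB (1.64 ± 0.43, adjusted p = 0.0270). For Umod, the NZB/W and NZM2410 changes differed (-0.40 ± 0.11, adjusted p = 0.0351), and for Lcn2 no pair passed (adjusted p = 0.435, 0.790 and 0.575). Strain tables differ in level and spread and were tested within each table first, and the ages of the other strains and the sex of any mouse were not stated. Ddx3y, a gene of the Y chromosome, was far higher in NZW/BXSB kidneys than in 16-week NZB/W and prenephritic NZM2410 kidneys. Strain and sex therefore cannot be told apart in the pairs with NZW/BXSB.

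Those counts moved with single samples. The 283 became 549 and 448 without 36-week NZB/W replicates 7 and 10, 156 and 176 without prenephritic NZM2410 replicates 1 and 2, and 138 and 1170 without nephritic NZM2410 replicates 3 and 4. The 951 became 572 without 16-week NZB/W replicate 4, 590, 496 and 598 without prenephritic NZW/BXSB replicates 1, 2 and 3, and 627, 541 and 1480 without nephritic NZW/BXSB replicates 2, 4 and 6. The 911 became 515, 534 and 532 without prenephritic NZM2410 replicates 1, 2 and 3, 507 and 1886 without nephritic NZM2410 replicates 3 and 4, and 1453 without nephritic NZW/BXSB replicate 6.

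The onset changes of NZB/W kidneys were compared with the late changes, which share no samples with them. Of the 281 genes that rose at onset, 192 also rose at 36 against 16 weeks (30.9 for independent lists), and of the 64 that fell, 20 also fell (9.81 for independent lists). Genes rising in both were 27, 105 and 109 without onset replicates 5, 3 and 4 and 121 without non-proteinuric replicate 7. Genes falling in both were 0, 9, 6 and 37 without onset replicates 5, 3, 4 and 6 and 11, 13, 10, 6, 10, 9 and 13 without non-proteinuric replicates 4 to 10. Across all genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.546 (jackknife standard error over arrays 0.258) and a Spearman correlation of 0.239 (0.291). Without onset replicate 5 these were 0.334 and 0.0136. Of the 345 onset genes, 318 had the same sign in NZM2410 (92.2%, against 63.7% of all genes) and 315 in NZW/BXSB (91.3%, against 67.7%).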

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

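Of the tests that weigh explanations here, those of the hybridization controls, of blood, of the correlation among adrenal genes and of strain differences against an equal change were chosen after the result was seen. The adrenal covariate was chosen after the data were seen but before its result, and the others before. Splits of the same samples, 100 per result with the real one included, were counted to see whether chance can be excluded.

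Taking the samples as exchangeable, chance was excluded for most gene counts. For 23 against 16 weeks and for NZB/W against NZM2410, another split called more genes than the real one, so 100 splits exclude it only weakly. As many genes as in the real split came in 1 of 100 splits for 36 against 16 weeks (4338, highest other 107), 1 for onset (345, highest other 10) and 2 for 23 against 16 weeks (3, highest other 33). In the other strains it was 1 for NZM2410 (4161, highest other 1801) and 1 for NZW/BXSB (3319, highest other 4). For strain differences the change common to both strains was taken out before splitting, and 2 splits gave as many for NZB/W against NZM2410 (283, highest other 623), 1 for NZB/W against NZW/BXSB (951, highest other 122) and 1 for NZM2410 against NZW/BXSB (911, highest other 2). Splits without that step take the effect of nephritis out of every strain and decide nothing between strains, with 3, 1 and 2 splits as large for these pairs (highest other 2347, 680 and 2232). They decide as little on the genes shared by 3 strains, with 1 (1243, highest other 0 by limma). Chance was not excluded for 36 weeks against onset, where 6 splits gave as many (382, highest other 1191), for the onset and late correlation, where 6 did (0.546, highest other 0.591), nor for any count of called lists. For the lists, brackets hold the real, highest other and median other counts. As many came in 9 splits for 36 against 16 weeks (24, 25 and 14) and 37 for onset (15, 24 and 11). Further counts were 14 for 23 against 16 weeks (9, 14 and 4) and 5 for 36 weeks against onset (25, 27 and 14). The other strains had 20 for NZM2410 (20, 24 and 12) and 18 for NZW/BXSB (18, 24 and 12). The split with 1191 genes, several times the real count, kept 7 of the 10 nephritic samples in place and points to a structure of the samples beyond the groups. Its first group held the 9 kidneys with phagocyte list means of 7.99 to 8.97 and 36-week replicate 9 at 7.55, and its second group the other 6, at 7.21 to 7.93. It called 795 to 1539 genes without each sample in turn and 1119 without onset replicate 5, so no single sample made it. The split with 33, against a real count of 3, kept 4 of the 11 non-proteinuric samples and so partly reverses the real grouping. Its samples were not examined, and a structure beyond the groups is not excluded there. Without 16-week replicates 1 to 3, whose control signals stood apart, the real grouping also called 33. Samples that share a title stem correlated at 0.437 in NZB/W, and the groups compared share 1 stem at onset and 0 at 23 against 16 weeks. With the stem as a random block 216 genes were called at onset and 0 by limma at 23 against 16 weeks, with 382 at an unadjusted p under 0.05, so the splits do not exclude the stem for the latter.

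Onset genes may follow the arrays. The hybridization controls differed between onset and non-proteinuric arrays by 0.67 and between 23- and 16-week arrays by -0.42, in signal that carries no kidney RNA. Against these controls as the whole cause, the 345 called genes shared their sign with NZM2410, where the controls differed by -0.0191 (exact permutation test, two-sided, p = 0.817), 28.5 percentage points more often than all genes, but the jackknife standard error of 9.68 points leaves it open. With the controls as a covariate all 345 kept their sign. Calls ended as the median size fell from 0.449 to 0.390 and the median standard error rose from 0.104 to 0.131. The 2 groups did not overlap in these controls, so that fit cannot tell them from onset. Without onset replicate 5 the median size was 82.9% of its value (0.372, error 0.105, 38 of the 345 still called, all 345 with an unadjusted p under 0.05), against 98.2% to 108% without each other onset kidney, so that 1 kidney cannot be told apart from a disease effect for the size of the calls, and disease stage, which the design names, stays open.

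The rise of Igkc, Jchain and Igha between 16 and 23 weeks was weighed against blood and adrenal tissue carried by the kidneys. Adrenal tissue is argued against, since with the adrenal score as a covariate the change of Igkc was 107% of its value without. For blood, the median change of the erythroid list plus 2 standard errors was 0.0915, far below the antibody genes, but Igha rose by 1.96, under the bound of 2 set for it, and only 2 of the 5 list members were marked expressed (Alas2 at 7.06 and Epor at 8.18, the other members at most 4.95), so blood stays open. Age is a biological difference that the design names, and it stays open and untested. The title stem stays open too, since with it as a random block 0 genes were called and the change of Igkc was 2.06.

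Adrenal cortex transcripts ranged from 5.33 to 10.48 as list means within non-proteinuric 23-week kidneys, for a mean of 8.07 and an SD of 2.05. Age between 16 and 23 weeks is argued against as the whole cause, since that SD was 1.59 times the difference of the group means of 1.29 (exact permutation test, two-sided, p = 0.101). Adrenal tissue left on some kidneys is a candidate explanation: over those 11 kidneys the list's genes had a median pairwise correlation of 0.984 and a lowest one of 0.718, with Hsd3b1 at a mean of 9.63 and Cyp21a1 at 9.04 against 8.0 and 7.32 at 16 weeks. All 8 list members were marked expressed in NZB/W kidneys and 0 stood in another list.

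Single samples stood apart from the others of their group in 45 of 481 groups of values tested, where chance gives about 1 in 20 groups (24.1). The 11 non-proteinuric 23-week NZB/W kidneys, the largest group, were not tested, since the test was set for smaller groups only. In 16-week NZB/W replicate 4, the hybridization controls were at 10.28 (others 9.30). In onset NZB/W replicate 5, the 3' minus 5' Gapdh signal was at 0.463 (others 0.0368), the mean of tubular injury genes at 9.61 (others 8.36), Slc34a1 at 11.49 (others 13.19), Umod at 13.43 (others 13.75), Icam1 at 9.08 (others 8.13), Lpar3 at 6.52 (others 8.29), Cyc1 at 12.44 (others 12.95), Ndufa9 at 11.30 (others 11.97), Idh3b at 11.20 (others 11.87), Sucla2 at 11.10 (others 11.58) and Ppargc1a at 9.40 (others 10.12). In 36-week NZB/W replicate 1, the hybridization controls were at 10.25 (others 9.25). In prenephritic NZM2410 replicate 5, the poly-A controls were at 5.80 (others 6.80), Serpina6 at 11.51 (others 12.15), Idh3b at 12.15 (others 12.29) and Cd2ap at 8.43 (others 8.93). In 16-week NZB/W replicate 1, the mean of mononuclear phagocyte genes was at 7.17 (others 6.88), Igkc at 12.90 (others 9.50), Jchain at 11.27 (others 8.91), Igkv6-15 at 6.79 (others 4.69), Ighm at 10.30 (others 7.43), Oasl2 at 7.42 (others 6.68), Ifit1 at 7.51 (others 6.54), H2-K1 at 10.13 (others 9.56), Asns at 6.38 (others 5.98), Cd14 at 8.36 (others 7.87), Slc8a1 at 8.01 (others 8.69) and Igha at 11.78 (others 9.59). In prenephritic NZM2410 replicate 2, the mean of adrenal cortex genes was at 9.48 (others 5.65) and Psmb8 at 8.45 (others 8.06). In nephritic NZM2410 replicate 5, the mean of adrenal cortex genes was at 8.48 (others 5.46). In prenephritic NZW/BXSB replicate 4, the mean of adrenal cortex genes was at 9.16 (others 6.30) and Col3a1 at 10.61 (others 9.27). In nephritic NZW/BXSB replicate 1, the mean of adrenal cortex genes was at 10.35 (others 6.52). In nephritic NZW/BXSB replicate 3, the mean of adipocyte genes was at 7.75 (others 8.94). In prenephritic NZM2410 replicate 3, Pcx was at 10.42 (others 10.64). In nephritic NZM2410 replicate 4, Asns was at 7.19 (others 8.01) and Ankrd6 at 6.60 (others 7.04). In prenephritic NZW/BXSB replicate 5, C3 was at 10.23 (others 9.34) and Cd2ap at 9.11 (others 8.86). In nephritic NZW/BXSB replicate 2, Hpd was at 7.26 (others 9.34), Havcr1 at 12.01 (others 10.45) and Cyp2d9 at 10.23 (others 11.08). In nephritic NZW/BXSB replicate 6, Slc34a1 was at 13.29 (others 13.72). The values in brackets are the means of the other samples of the group.

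The change from prenephritic to nephritic kidneys differed between strains, by a test of the difference itself, for the 4 clearest genes of each pair. That change holds age as well as nephritis in NZB/W. In the pairs with NZW/BXSB, sex cannot be told apart from strain. Values are the first strain's log2 fold change minus the second's. For NZB/W against NZM2410 these were Havcr1 (-4.43), Gstt1 (-1.0), Cfi (-1.36) and Ankrd6 (-0.94). For NZB/W against NZW/BXSB they were Cyp2d9 (3.05), Npl (-1.64), Pla2g5 (-1.06) and Pcdh7 (-0.84). For NZM2410 against NZW/BXSB they were Havcr1 (4.19), Cyp2d9 (2.77), Kcne1l (-1.59) and Aldh1a1 (1.77).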

How the results depend on the processing

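The covariates, the expressed genes, 16-week replicates 1 to 3 left out, fold changes scaled by table spread and samples left out for overlaps and differences were chosen after the data were seen, the other alternatives before. Over all alternatives, lists kept direction and call in 2673 of 2885 cases, lost the call in 208 and turned in 4. Named genes kept both in 13782 of 15143 cases, with 1229 lost, 131 gained and 1 turned. The 12 clearest strain differences, 4 per pair, kept both in 364 of 364 cases. Those cases cover only 1 fit of all samples, the dim and expressed-gene filters, scaling by table spread and samples left out. Other normalizations, array weights, blocks and covariates were not applied to strain differences. These genes were also picked by the smallest p in the same data, which favours stability. The other strain differences named were not rerun gene by gene. Where values moved, the cause was not tested except as given. The series table is identical to the strain tables, so that alternative was void, and its 560 cases of named genes could only be unchanged. The title stem block could not be estimated in NZM2410 (correlation 0.437 in NZB/W, 0.296 in NZW/BXSB). Signal near the floor limits dim genes: 9885 genes remained without the dimmest 40 percent.

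Array weights called 6542 for 36 against 16 weeks, 2167 for onset, 3697 for 23 against 16 weeks, 2352 for 36 weeks against onset, 6449 for NZM2410 and 5898 for NZW/BXSB. With the title stem as a random block, the first 4 were 2731, 216, 0 by limma (382 unadjusted) and 122. With only the 2 groups, which drops the other groups' spread (SD of phagocyte means 0.12 at 16 weeks, 0.53 at 36), onset had 1141, 23 against 16 weeks 19 and 36 weeks against onset 1. Covariates gave, for 36 against 16 weeks, 2527 with the Gapdh signal. For onset they gave 109 with the hybridization controls (52 shared with the 345), 189 with Gapdh and 209 with the adrenal score. For 23 against 16 weeks it was 1 with the hybridization controls, and for 36 weeks against onset 8, 110 and 35. Leaving out 16-week replicates 1 to 3 gave 33 for 23 against 16 weeks, quantile normalization 205 for 36 weeks against onset, and an adjusted p under 0.01 gave 518 shared genes. With an estimated correlation camera called 7 lists for 36 against 16 weeks and 0 in each other comparison. At an unadjusted p under 0.05 those were 6 for onset, 2 for 23 against 16 weeks, 4 for 36 weeks against onset, 6 for NZM2410 and 7 for NZW/BXSB. For 23 against 16 weeks fry called 0 lists (4 unadjusted) and only the 2 groups 17.

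Replicate numbers do not pair the samples: the deviations of same-numbered samples correlated over 0.1 in 1 of 8, 3 of 6, 1 of 8, 1 of 6, 1 of 5 and 2 of 6 pairs of the 6 comparisons. Not every sample correlated best with its own number. With the replicate block, fitted to fewer samples, 3142 genes were called for 36 against 16 weeks, 0 for onset by limma (2974 at an unadjusted p under 0.05, and 10 called in the same samples without it) and 1 for 23 against 16 weeks (7 without it, and 15 lists). It gave 941 for 36 weeks against onset (1 without it), 3611 for NZM2410 and 2328 for NZW/BXSB.

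With each sample left out in turn, called genes went from 3625 to 4837, 39 to 452, 2 to 5, 19 to 2008, 3231 to 5017 and 2358 to 3519 in 36 against 16 weeks, onset, 23 against 16 weeks, 36 weeks against onset, NZM2410 and NZW/BXSB. Called lists went from 22 to 25, 13 to 16, 7 to 12, 24 to 27, 19 to 22 and 18 to 19. Shared genes went from 1023 to 1335, strain differences from 138 to 1170, 496 to 1480 and 507 to 1886. The onset and late Pearson correlation went from 0.334 to 0.614, Spearman from 0.0136 to 0.309, genes rising in both from 27 to 248 and falling in both from 0 to 37 (limma). Without onset replicate 5 onset had 39 genes and 36 weeks against onset 2008, and the 4 lowest values of onset against late came without it, while 36 weeks against onset had 19 without onset replicate 2. Of strain differences, those with NZM2410 were lowest without its nephritic replicate 3 and highest without replicate 4, and NZB/W against NZW/BXSB was lowest without prenephritic replicate 2 and highest without nephritic replicate 6 of NZW/BXSB. Turned in direction were Umod at 36 against 16 weeks under quantile normalization (a change of 0.000866) and the proximal tubule list at onset without onset replicate 5 (adjusted p = 0.784, range 0.00369 to 0.784 over samples left out). So were, by adjusted p, the matrix (0.983) and oxidative phosphorylation (0.276) lists at 23 against 16 weeks with the hybridization controls as covariate, and the adrenal cortex list at 36 weeks against onset with its own score as covariate (0.612), which that construction removes.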

Other observations

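No hypothesis is put forward here, and of the tests in this part the Gapdh covariate was chosen after the data were seen. Fixed lists were compared between strains by how far their members changed from prenephritic to nephritic kidneys. Counts are of members whose change differed at an adjusted p under 0.05 over all genes, and medians are of the first strain's change minus the second's. Of the 33 lists, the 9 with at least 5 such members in some pair are given, each for NZB/W against NZM2410, NZB/W against NZW/BXSB and NZM2410 against NZW/BXSB, in that order. Over all 16475 genes, 283, 951 and 911 differed in these pairs. Of tubular injury genes 8 of 26 (median -0.76), 1 of 26 (median -0.14) and 7 of 26 (median 0.63) differed, of matrix genes 1 of 32 (median 0.29), 5 of 32 (median -0.36) and 13 of 32 (median -0.42), and of class II genes 0 of 12 (median -0.62), 2 of 12 (median 0.54) and 7 of 12 (median 1.10). Of NF-kB targets 3 of 22 (median -0.25), 0 of 22 (median 0.09) and 5 of 22 (median 0.43) differed, and of fatty acid oxidation genes 0 of 27 (median -0.17), 1 of 27 (median 0.11) and 5 of 27 (median 0.33). Of B cell genes 4 of 13 (median 0.49), 7 of 13 (median 0.49) and 0 of 13 (median 0.07) differed and of plasma cell genes 5 of 13 (median 0.48), 6 of 13 (median 0.63) and 3 of 13 (median -0.05). The plasma cell median against NZM2410 did not describe its leading genes, since Igkc rose by 3.96 in NZB/W and 4.83 in NZM2410, and Jchain by 3.71 and 3.81. Of oxidative phosphorylation genes 0 of 27 (median -0.06), 9 of 27 (median -0.32) and 4 of 27 (median -0.26) differed, and of proximal tubule markers 2 of 25 (median 0.05), 6 of 25 (median -0.41) and 8 of 25 (median -0.53). Among lists not given, camera on the differences had the lowest adjusted p for endothelium between NZB/W and NZM2410 (4.91e-08, 2 of 14 differing, median 0.44). Cell cycle genes came close, between NZB/W and NZW/BXSB (4.29e-07, 1 of 24, median -0.66) and NZM2410 and NZW/BXSB (8.86e-08, 1 of 24, median -0.62). Next were citrate cycle (4.99e-06) and class I genes (5.52e-06) between NZM2410 and NZW/BXSB, and T cell markers between NZB/W and NZW/BXSB (1.48e-05). These tests used the preset correlation of 0.01 only. An estimated correlation, which ended 104 of the 111 list calls within strains, was not run on the differences. The ages of NZM2410 and NZW/BXSB mice and the sex of any mouse were not stated, and neither was tested. The Y-chromosome gene Ddx3y, however, was far higher in NZW/BXSB kidneys than in 16-week NZB/W and prenephritic NZM2410 kidneys. Strain and sex therefore cannot be told apart in the pairs with NZW/BXSB. Age stays open behind the differences of every pair.

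Lists that camera did not call in NZM2410 or NZW/BXSB still held members that passed. In NZM2410, of collecting duct principal cell markers 3 of 9 rose and 1 fell (5 and 1 adjusted over the list alone) and of thick ascending limb markers 2 of 10 rose and 1 fell (2 and 2 adjusted over the list alone). There, of B cell markers 3 of 13 rose and 1 fell (3 and 1 adjusted over the list alone) and of intercalated cell markers 1 of 8 rose and 2 fell (1 and 3 adjusted over the list alone). In NZW/BXSB, of endothelial markers 0 of 14 rose and 3 fell (2 and 6 adjusted over the list alone) and of glycolysis and hypoxia genes 2 of 13 rose and 3 fell (2 and 3 adjusted over the list alone). In that strain, of thick ascending limb markers 2 of 10 rose and 2 fell (2 and 2 adjusted over the list alone) and of T cell markers 2 of 18 rose (0 adjusted over the list alone).

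Ddx3y, a gene of the Y chromosome, was at 9.46 ± 0.24 in prenephritic and 8.82 ± 0.39 in nephritic NZW/BXSB kidneys, and fell by 0.64 ± 0.16 (adjusted p = 0.0159, 6 of 6 samples). The call was lost with the title stem as a random block (adjusted p = 0.0697) and with the Gapdh signal as a covariate (0.0566). Its level was 3.88 ± 0.05 in 16-week NZB/W and 3.33 ± 0.04 in prenephritic NZM2410 kidneys, each level within its own table. The mean of the 4 sex-linked genes was 7.80 and 7.64 in prenephritic and nephritic NZW/BXSB kidneys and 5.21 to 5.69 in the groups of the other strains. The heat shock gene Hspa1a ranged from 9.14 to 13.96 among the 6 prenephritic NZW/BXSB kidneys (11.72 ± 1.58) and was at 9.11 ± 0.45 in the nephritic ones.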
